A study of Alligator mississippiensis with 17 samples.

How the data were processed

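RNA sequencing of tooth tissue from young, laboratory-raised, untreated American alligators was taken as deposited by the authors. The values are RPKM, deposited by the authors, which scale reads to gene model length and library alignments. Of the 17 libraries, 12 came from dental lamina at pre-initiation (PIS, n = 5), initiation (IS, n = 3) and early growth (EG, n = 4), and 5 came from replacement teeth (RT). Sample titles and descriptions gave the groups, and each deposited column matched 1 of them. A separate label field reads pre-initiation for every sample and was not used here. Per the submitters' processing notes, TopHat2 2.1.0 and Partek 3 were used, with no role given to either. The genome build and gene annotation are not given in the sources used here, so positions are not reported. Strand is not stated, so overlapping or antisense transcription remained uncertain, and gene names, including paralog suffixes such as DES.1 and names ending in L, are those of the table.

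The table held 20703 genes, of which 6042 had bare model identifiers and 782 LOC numbers, and 11479 symbols matched the RefSeq gene table. AMELX, AMEL and DSPP, fixed as genes of interest, are not listed under those symbols. Depth ranged from 9667270 alignments (PIS replicate 3) to 37747400 (EG replicate 4). In low genes the values stepped by whole reads of that depth, within 1.91% between libraries. Counts were not reconstructed, so no counting intervals are given.

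Values were analysed as log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (group-means fit, contrasts, empirical Bayes with a mean-variance trend). Genes with at least 1 RPKM in at least 3 libraries of a fit were tested, 12684 in the dental lamina fit and 12904 in the fit of all 17 libraries. IS versus PIS, EG versus IS, EG versus PIS and an F test among the stages came from the dental lamina fit, and RT was set against the unweighted mean of the 3 stage means in the larger fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Because the median gene shifted between groups, counts of called genes and list members are given beside those, or the number kept, after median-ratio scaling (factors 0.768 to 1.24).

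There were 29 gene lists of pathways, tissues and cell types, written before the data were examined, as were the groups, tests and the rule for naming genes. Each was tested in each of the 4 comparisons with camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry, which asks whether a list moves one way without comparing it with other genes. Camera compares a list with other genes, so where the median gene rose a list could be placed lower with a median above 0. Members called over all genes are given beside members called when adjusted over the list alone. The rule named, per comparison, the 8 greatest rises and 8 greatest falls among called genes with a symbol whose groups did not overlap. It also named up to 3 called members of each list passing camera, the called member with the smallest p of each other list, and a set of anchor genes (among them SOX2, SHH, LEF1, AXIN2, BMP4 and MSX1). Results of some genes that the rule named are not reported here.

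The fits were tested on simulated data with the same group sizes and 200 changed genes. They recovered 60% to 81% of changes of 1 on the log2 scale and 95% to 97% of changes of 2, with 5 to 9 unchanged genes called and 0 of 29 lists called. The simulated genes varied independently of each other, so the list result does not test the preset correlation. Alternatives were other pseudocounts (0.1 and 1), no filter, a stricter filter (mean RPKM of 5), median-ratio and quantile scaling, array weights, no trend, a minimum log2 fold change of 1, other sets of libraries in the fit, other dental lamina references for RT, a replicate block and each library left out in turn. Leaving out PIS replicates 4 and 5 together, or RT replicates 3 and 5 together, and the estimated correlation after scaling, were chosen after seeing the data. Count-based tools were not used because the values are RPKM.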

Results

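The American alligator replaces its teeth throughout life, and each new tooth buds from the dental lamina, an epithelial strand beside the tooth that it will replace. Expression was compared between dental lamina before tooth initiation (PIS, 5 libraries), at initiation (IS, 3 libraries) and in early growth (EG, 4 libraries), and between these stages and replacement teeth (RT, 5 libraries). Group values are mean RPKM ± SD over those libraries. Fold changes are differences of log2(RPKM + 0.5), which understate changes of genes near 0. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples.

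Along the first principal component (39.8% of the variance), the RT libraries lay at 42.3 to 70.4, the EG libraries at 3.98 to 24.5, the IS libraries at -37.4 to -17.9 and the PIS libraries at -58.1 to -33.4. The second component (28.1%) spread the RT libraries from -10.05 to 62.2 and set PIS replicate 5 at 56.2, beside 6.87 to 23.8 in the other PIS libraries. Spearman's rho across genes ranged from 0.941 to 0.970 between PIS libraries, from 0.972 to 0.980 between IS, from 0.978 to 0.986 between EG and from 0.935 to 0.974 between RT libraries. Genes are not independent replicates in these coefficients. Of 12684 genes tested in dental lamina, 5764 differed among the stages by limma's F test (3548 after median-ratio scaling). As deposited, 3621 of the 5764 had their highest mean in EG and 733 in PIS. After scaling, 1296 of the 3548 had their highest mean in EG and 1613 in PIS, so the stage holding most of the peaks depended on the scaling.

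**Figure D1:**
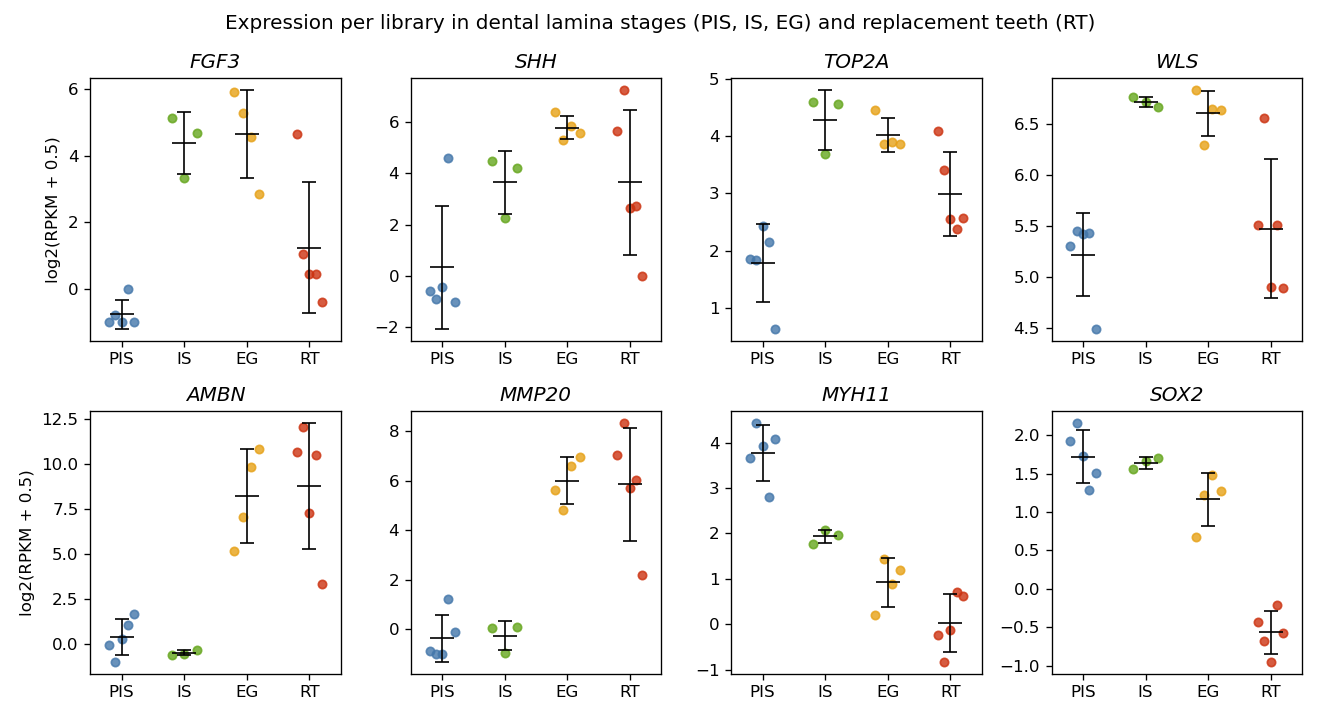
Expression of 8 genes, as log2(RPKM + 0.5), in each library of the dental lamina stages PIS, IS and EG and of replacement teeth (RT); points are libraries and bars show the mean and SD of the log2 values. FGF3 reached 23 ± 12.5 RPKM at initiation and AMBN 739 ± 846 RPKM in early growth, while MYH11 was highest before initiation at 14.1 ± 5.35 RPKM.

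At initiation, the dental lamina expressed 40 of 42 cell cycle genes above their level before initiation. FGF3, EDAR and 7 of 14 WNT target genes were among the genes that rose, and 14 of 28 endothelial and mural cell genes fell. In total, 2880 genes were higher and 286 lower in IS than in PIS. The median gene was 0.28 higher on the log2 scale, and after median-ratio scaling removed this shift 809 genes were higher and 668 lower. The 809 higher genes and 282 of the lower ones were called in both analyses. Without IS replicate 1 the count of called genes fell from 3166 to 978, and without IS replicate 3 to 1309. It was 4850 with array weights, 1494 with only PIS and IS in the fit, 1992 with a stricter filter, 1546 after quantile normalization and 797 at a log2 fold change of at least 1.

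FGF3, which encodes a fibroblast growth factor of developing teeth, rose from 0.115 ± 0.216 RPKM in PIS to 23 ± 12.5 RPKM in IS, a log2 fold change of 5.13 ± 0.57 (SE, adjusted p = 0.000401). EDAR, the ectodysplasin receptor gene, rose from 0.995 ± 1.18 to 11.7 ± 3.54 RPKM, by 3.29 ± 0.47 (SE, adjusted p = 0.00123). DLK1, the gene of a secreted and membrane-bound Notch pathway modulator, rose from 0.0892 ± 0.103 to 13.5 ± 8.13 RPKM (4.36, adjusted p = 0.00012). NPTX2 (4.14, adjusted p = 0.00282), SAMD10 (3.60, adjusted p = 0.00215), AKR1D1 (3.55, adjusted p = 0.00191) and BEGAIN (3.43, adjusted p = 0.00021) were also among the genes with the greatest rises. The naming rule required ranges without overlap of the greatest rises but not of EDAR, which was named through its lists. The ranges of PIS and IS libraries did not overlap for any of these 7 genes. The same held for 2673 of the 3166 called genes and 3435 of the 12684 tested. For SHH the log2 fold change was 3.31, adjusted p = 0.0376, but PIS replicate 4 held 23.5 RPKM beside at most 0.241 in the other PIS libraries. Without PIS replicate 4 the change was 4.38 (adjusted p = 0.000212), and without PIS replicates 4 and 5 it was 4.29 (0.000516). With that library in, the SHH call was lost after median-ratio scaling (3.16, adjusted p = 0.0763). It was also lost without 1 other library, with an adjusted p of 0.0598 without PIS replicate 1, 0.0713 without PIS 2, 0.0601 without PIS 3, 0.0657 without PIS 5, 0.146 without IS 1, 0.129 without IS 3, 0.0519 without EG 3 and 0.05002 without EG 4. It was 0.0683 without an expression filter, 0.0767 after quantile normalization, 0.0943 with all 17 libraries in the fit and 0.0892 with only PIS and IS in it. SOX2 (log2 fold change -0.08, adjusted p = 0.803), BMP4 (0.20, adjusted p = 0.696) and MSX1 (-0.17, adjusted p = 0.652) were not called, and for all 3 the sign changed under other settings.

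WNT target genes moved up beyond other genes, with 7 of 14 measured members higher and 0 lower (8 and 0 adjusted over the list alone), and 6 of the 7 also called after scaling (camera adjusted p = 0.00428, adjusted p = 0.489 with an estimated correlation). Besides EDAR, they included the transcription factor genes SP5 (2.02, adjusted p = 0.0029) and TCF7 (1.34, adjusted p = 0.00746), with the SP5 call lost when all 17 libraries entered the fit (adjusted p = 0.0514). The transcription factor gene LEF1 rose from 11.4 ± 5.86 to 24.5 ± 3.84 RPKM (1.24, adjusted p = 0.0328), a call lost after median-ratio scaling (0.96, adjusted p = 0.106). Its adjusted p was 0.0547 without PIS replicate 3, 0.092 without IS 1, 0.0895 without IS 2 and 0.0813 without IS 3. It was 0.0578 without an expression filter, 0.084 after quantile normalization and 0.077 with only PIS and IS in the fit. AXIN2 was not called (0.41, adjusted p = 0.175). WLS, whose product carries WNT ligands to the cell surface, rose from 37.8 ± 9.01 to 105 ± 3.8 RPKM (1.50, adjusted p = 0.000907), and the WNT feedback inhibitor gene NKD1 rose as well (1.30, adjusted p = 0.000485). The gene of the activin subunit INHBA (1.30, adjusted p = 0.00076) and that of the BMP family ligand BMP3 (2.11, adjusted p = 0.00138) were both higher in IS.

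Cell cycle and DNA replication genes were higher for 40 of 42 members and lower for 0 (40 and 0 adjusted over the list alone), and 36 of the 40 were also called after scaling (camera adjusted p = 1.57e-17, adjusted p = 0.479 with an estimated correlation). TOP2A, the topoisomerase gene of dividing cells, rose from 3.21 ± 1.42 to 19.8 ± 6.44 RPKM (2.51, adjusted p = 0.00104), with CCNB1 (2.52, adjusted p = 0.00339) and CENPA (2.17, adjusted p = 0.000758). Oxidative phosphorylation genes were higher for 15 of 31 members and lower for 0 (19 and 0 adjusted over the list alone; camera adjusted p = 0.00284, adjusted p = 0.506 with an estimated correlation), but only 3 of the 15 were called after scaling, among them ATP5B (0.58, adjusted p = 0.00913), and camera did not call the list then (0.221). Leukocyte genes were higher for 10 of 19 and lower for 0 (11 and 0 adjusted over the list alone), 6 of them also after scaling (camera adjusted p = 0.0428, adjusted p = 0.479 with an estimated correlation). The macrophage genes CSF1R (1.60, adjusted p = 0.00441) and C1QA (1.33, adjusted p = 0.00398) were among them.

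Endothelial and mural cell genes were lower for 14 of 28 members and higher for 0 (16 and 0 adjusted over the list alone), all 14 also after scaling (camera adjusted p = 6.4e-20, adjusted p = 0.479 with an estimated correlation). MYH11, the smooth muscle myosin gene, fell from 14.1 ± 5.35 to 3.33 ± 0.39 RPKM (-1.84, adjusted p = 0.00339), and the smooth muscle actin gene ACTG2 from 119 ± 42.1 to 29.8 ± 3.85 RPKM (-1.91, adjusted p = 0.00853). The lymphatic endothelial gene LYVE1 was lower too (-1.64, adjusted p = 0.00474). SBSPON had the greatest fall among named genes (-2.30, adjusted p = 0.00586). Of nerve and Schwann cell genes, 4 of 13 were lower and 1 higher (4 and 1 adjusted over the list alone, 4 and 1 after scaling; camera adjusted p = 5.55e-05, adjusted p = 0.479 with an estimated correlation). Camera placed 5 further lists below other genes. These were fibroblasts (2 higher and 0 lower of 31, camera adjusted p = 0.00204), cartilage (0 of 15 called, 0.0349) and skeletal muscle (0 of 5, 0.0409). The others were cell adhesion and matrix remodelling (4 higher and 1 lower of 41, 0.0428) and red blood cells (0 higher and 1 lower of 7, 0.0473). With an estimated correlation the adjusted p values were 0.504, 0.504, 0.479, 0.504 and 0.479. Adjusted over the list alone, these lists had 2 and 0, 0 and 0, 0 and 0, 4 and 1, and 2 and 2 members called higher and lower. After scaling they had 2 and 1, 0 and 0, 0 and 1, 3 and 2, and 0 and 2, and camera called none of the 5 (0.0829, 0.415, 0.221, 0.377 and 0.415). The adhesion list's median (0.12) and the cartilage list's (0.03) were above 0 while the test placed them below other genes, and the red blood cell list had a median of -0.54 and a mean of 0.39. The fibroblast list had a median of -0.11 and a mean of 0.04.

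Enamel formation genes were higher in the early growth libraries of dental lamina than at initiation. Whether the lamina itself or tissue dissected with it expressed them was not tested. The structural enamel matrix genes AMBN and ENAM and the enamel protease gene MMP20 went from near 0 at initiation to high expression. Camera placed lists of mesenchymal, fibroblast and leukocyte genes below other genes at the preset correlation but not with an estimated one (adjusted p = 0.338, 0.289 and 0.103), with 0, 2 and 0 members called over all genes. Between IS and EG 273 genes were called, 208 higher and 65 lower in EG. After scaling, 234 were called, 167 higher and 67 lower, and 163 and 57 were called in both analyses. The median gene was 0.05 higher. The count depended on the fit and on single libraries. It was 4015 with array weights (2405 higher and 1610 lower), 940 with only IS and EG in the fit, 107 with all 17 libraries and 119 with a stricter filter. It was 597 without PIS replicates 4 and 5, chosen after seeing the data, and 439 without PIS replicate 5, which belongs to neither group but enters the shared spread. It was 139, 69 and 106 without IS replicates 1, 2 and 3, and 109, 180, 87 and 146 without EG replicates 1, 2, 3 and 4.

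AMBN rose from 0.203 ± 0.0721 RPKM in IS to 739 ± 846 RPKM in EG, a log2 fold change of 8.75 ± 1.06 (SE, adjusted p = 0.00112). ENAM rose from 0.0108 ± 0.0188 to 271 ± 239 RPKM, by 8.44 ± 0.64 (SE, adjusted p = 2.71e-05), and MMP20 from 0.375 ± 0.306 to 74.1 ± 43.6 RPKM, by 6.26 ± 0.58 (SE, adjusted p = 0.000139). AMBN differed widely between the EG libraries, from 35.3 RPKM in replicate 1 to 1858 RPKM in replicate 4. In the enamel list, 5 of 8 measured members were higher and 0 lower (7 and 0 adjusted over the list alone), 4 of them also after scaling (camera adjusted p = 1.23e-11, adjusted p = 0.103 with an estimated correlation). SCNN1D, the gene of an epithelial sodium channel subunit, rose from 0.0499 ± 0.0464 to 84.4 ± 31.7 RPKM (7.17, adjusted p = 4.85e-05). The calcium-binding protein gene CALB1 (6.84, adjusted p = 0.00439), the creatine kinase gene CKM (5.17, adjusted p = 0.00461) and the transcription factor gene SOX21 (4.14, adjusted p = 2.71e-05) rose too. With all 17 libraries in the fit CALB1 and SOX21 were not called (adjusted p = 0.0931 and 0.052). The Notch ligand gene DLL1 rose from 3.0 ± 0.488 to 22.1 ± 6.48 RPKM (2.65, adjusted p = 5.42e-05). The naming rule required ranges without overlap of the greatest rises but not of DLL1, which was named through a list. The ranges of IS and EG libraries did not overlap for any of these 8 genes. The same held for all 273 called genes and for 2916 of the 12684 tested. NR2F1, a nuclear receptor gene, fell from 8.19 ± 1.44 to 2.0 ± 0.599 RPKM (-1.81, adjusted p = 0.00456). CGA, the gene of the glycoprotein hormone alpha subunit, had risen from 0.30 ± 0.371 RPKM in PIS to 8.49 ± 3.08 in IS and was at 1.26 ± 0.596 RPKM in EG (-2.35, adjusted p = 0.00593), a call lost with a pseudocount of 0.1 (adjusted p = 0.0597). None of SHH (2.12, adjusted p = 0.398), SOX2 (-0.48, adjusted p = 0.353), LEF1 (-0.90, adjusted p = 0.307), MSX1 (-0.81, adjusted p = 0.179), AXIN2 (-0.32, adjusted p = 0.571) and BMP4 (0.22, adjusted p = 0.852) was called in the main fit. SHH was called higher without PIS replicate 4 (adjusted p = 0.0248), without PIS replicates 4 and 5 (0.0234), with only IS and EG in the fit (0.0357) and with array weights (0.0179). LEF1 was called lower with only IS and EG in the fit (0.0148) and with array weights (0.00955), which also called MSX1 (0.00313) and AXIN2 (0.0429) lower.

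The fibroblast list was lower by camera with 0 members higher and 2 of 31 lower (0 and 7 adjusted over the list alone, 0 and 1 after scaling; camera adjusted p = 9.16e-12, adjusted p = 0.289 with an estimated correlation). FAP, a fibroblast protease gene, was among them (-1.01, adjusted p = 0.00878), a call lost without IS replicate 2 (adjusted p = 0.0639) and with all 17 libraries in the fit (0.211). The fibroblast list score was 0.20, 0.99 and 0.32 in IS replicates 1 to 3. It was -0.55, 0.013, -0.015 and 0.093 in EG replicates 1 to 4, so IS replicate 2 and EG replicate 1 set much of the difference. Leukocyte genes had 0 of 19 members called over all genes and 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.000124, adjusted p = 0.103 with an estimated correlation). Lists for mesenchymal transcription factors (camera adjusted p = 0.000353), immediate early genes (0.000628), ribosomal proteins (3.33e-13), endothelial and mural cells (0.000187), nerve (0.025) and cell cycle (0.0304) were also placed lower with 0 members called over all genes. Adjusted over the list alone, 3 mesenchymal members were lower and 0 members of the other 5 lists were called. After scaling 0 members of the leukocyte list and these 6 lists were called over all genes, and camera no longer called the nerve list (0.0735). With an estimated correlation the adjusted p values of the 6 were 0.338, 0.743, 0.641, 0.743, 0.743 and 0.814.

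Early growth and pre-initiation lamina are the ends of the sampled cycle, and of the pairs of dental lamina stages they had the most called genes. Enamel and proliferation genes, SHH and SP6 were higher in early growth. Lower genes included 19 of 28 endothelial and mural, 8 of 13 nerve and Schwann cell and 14 of 31 fibroblast genes. Of the 6404 genes called, 5443 were higher and 961 lower in EG, with the median gene 0.34 higher on the log2 scale. After median-ratio scaling 2126 were higher and 1958 lower, and 2126 and 961 were called in both analyses. The count was 4025 after quantile normalization, 3982 with a stricter filter and 1725 at a log2 fold change of at least 1.

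ENAM rose from 0.129 ± 0.14 RPKM in PIS to 271 ± 239 RPKM in EG, a log2 fold change of 8.16 ± 0.56 (SE, adjusted p = 1.35e-05). SHH rose from 4.78 ± 10.4 to 56.1 ± 18.7 RPKM, by 5.43 ± 0.96 (SE, adjusted p = 0.000895). SP6, a transcription factor gene of dental epithelium, rose from 4.35 ± 9.38 to 118 ± 22.3 RPKM (6.51, adjusted p = 0.000296). For SHH and SP6 most of the PIS mean came from PIS replicate 4. Without it the changes were 6.49 (adjusted p = 2.54e-06) and 7.53 (1.06e-06), and without PIS replicates 4 and 5 they were 6.40 (8.88e-06) and 7.45 (5.12e-06). SOX21 (3.88, adjusted p = 1.58e-05), the growth factor gene BMP7 (3.39, adjusted p = 0.000109), EDAR (3.14, adjusted p = 0.000239), DLL1 (2.08, adjusted p = 4.68e-05) and TCF7 (2.26, adjusted p = 0.000118) rose as well. All 8 measured enamel genes were higher (8 adjusted over the list alone), 7 also after scaling (camera adjusted p = 0.000188, adjusted p = 0.442 with an estimated correlation). Of 42 cell cycle genes, 40 were higher and 0 lower (40 and 0 adjusted over the list alone), 38 also after scaling (camera adjusted p = 3.07e-09, adjusted p = 0.442 with an estimated correlation). Oxidative phosphorylation genes were higher for 23 of 31 (23 adjusted over the list alone), 6 of them also after scaling (camera adjusted p = 0.00358, adjusted p = 0.502 with an estimated correlation), when camera did not call the list (0.248). MSX1, the mesenchymal transcription factor gene, fell from 60.5 ± 16 to 29.98 ± 8.41 RPKM (-0.98, adjusted p = 0.0063). LEF1 (0.34, adjusted p = 0.424), AXIN2 (0.09, adjusted p = 0.731, negative after scaling) and BMP4 (0.42, adjusted p = 0.296) were not called. SOX2 was at 2.87 ± 0.79 RPKM in PIS and 1.78 ± 0.498 in EG (-0.56, adjusted p = 0.0348). The SOX2 call was lost without PIS replicate 1 (adjusted p = 0.0657), PIS 2 (0.0768), PIS 3 (0.0537), EG 1 (0.124), EG 2 (0.0561) or EG 4 (0.0527). It was also lost without an expression filter (adjusted p = 0.0612), with array weights (0.118) and with only PIS and EG in the fit (0.0591).

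Endothelial and mural cell genes were lower for 19 of 28 members and higher for 1 (20 and 1 adjusted over the list alone), all 19 lower also after scaling (camera adjusted p = 8.54e-21, adjusted p = 0.368 with an estimated correlation). The smooth muscle genes MYH11 (-2.85, adjusted p = 7.72e-05), TAGLN (-2.37, adjusted p = 0.000517) and ACTG2 (-2.82, adjusted p = 0.000234) and the endothelial gene VWF (-2.14, adjusted p = 0.0013) were lower. The 1 higher member, the smooth muscle gene CNN1, looked up after its values were seen, was at 31.6 ± 3.5 RPKM in PIS and 40.2 ± 3.58 in EG (0.35, adjusted p = 0.0364) and was not called after scaling (adjusted p = 0.994). CFD, the complement factor D gene, fell from 477 ± 286 to 52.3 ± 23.2 RPKM (-3.06, adjusted p = 0.000699). Nerve and Schwann cell genes were lower for 8 of 13 and higher for 2 (8 and 2 adjusted over the list alone, 9 and 1 after scaling; camera adjusted p = 1.37e-06, adjusted p = 0.442 with an estimated correlation), with SOX10 among them (-2.45, adjusted p = 0.00187). Fibroblast and interstitial matrix genes were lower for 14 of 31 and higher for 2 (14 and 2 adjusted over the list alone, 20 and 1 after scaling; camera adjusted p = 1.16e-12, adjusted p = 0.368 with an estimated correlation), with MFAP5 (-2.54, adjusted p = 0.000624), OGN (-1.98, adjusted p = 0.000808) and PRRX1 (-1.62, adjusted p = 0.00177). The secreted WNT inhibitor genes SFRP2 (-2.77, adjusted p = 0.000111), SFRP4 (-3.00, adjusted p = 0.00408) and FRZB (-1.74, adjusted p = 0.000103) fell. Camera also placed 4 other lists lower. Parentheses give higher and lower counts adjusted over the list alone, then those after scaling. Mesenchymal transcription factors were 4 higher and 5 lower of 20 (4 and 5, 2 and 6) and adhesion and matrix remodelling genes 11 higher and 10 lower of 41 (11 and 10, 6 and 14). Immediate early and heat shock genes were 4 higher and 3 lower of 29 (2 and 3, 2 and 4) and ribosomal protein genes 1 higher and 8 lower of 56 (0 and 0, 0 and 45). Their camera adjusted p values were 0.0211, 0.00674, 0.00823 and 5.35e-10, with 0.442, 0.442, 0.65 and 0.455 with an estimated correlation. After scaling camera called only the ribosomal list of the 4 (2.54e-14, beside 0.304, 0.248 and 0.481), and the number of lower ribosomal protein genes depended on the scaling. The medians of the mesenchymal (0.14) and immediate early (0.33) lists were above 0 although the test placed them below other genes, and the adhesion list had a median of -0.04 and a mean of 0.30.

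The other lists were not called by camera between EG and PIS as deposited, and each had members that changed. Parentheses give higher and lower counts adjusted over the list alone, then those after scaling, where most rises shrank and the balance of the WNT inhibitor, TGF-beta and activin, dentin and leukocyte lists turned. After scaling camera called the WNT target list higher at the preset correlation (0.0445) but not with an estimated one (0.795). WNT pathway genes were 19 higher and 3 lower of 41 (19 and 4, 14 and 4) and WNT inhibitors 6 higher and 5 lower of 15 (6 and 5, 4 and 6). WNT targets were 8 higher and 1 lower of 14 (8 and 1, 6 and 1) and hedgehog genes 7 higher and 1 lower of 15 (7 and 1, 2 and 1). BMP genes were 10 higher and 5 lower of 28 (10 and 5, 6 and 6) and TGF-beta and activin genes 6 higher and 5 lower of 17 (8 and 5, 3 and 5). FGF genes were 11 higher and 2 lower of 22 (11 and 2, 8 and 3) and Notch genes 5 higher and 5 lower of 15 (5 and 5, 3 and 5). Ectodysplasin and NF-kB genes were 6 higher and 1 lower of 15 (6 and 1, 2 and 1). Dental epithelium genes were 9 higher and 1 lower of 16 (9 and 1, 4 and 1) and stem cell niche markers 4 higher and 4 lower of 18 (4 and 4, 2 and 5). Dentin and bone matrix genes were 6 higher and 3 lower of 20 (6 and 3, 5 and 7) and hypoxia and glycolysis genes 9 higher and 0 lower of 21 (9 and 0, 4 and 0). Leukocyte genes were 6 higher and 1 lower of 19 (6 and 1, 1 and 3) and osteoclast genes 6 higher and 1 lower of 11 (6 and 1, 5 and 1). Red blood cell genes were 2 higher and 2 lower of 7 (2 and 2, 2 and 2) and surface epithelium genes 7 higher and 0 lower of 12 (7 and 0, 2 and 0). Cartilage genes were 4 higher and 2 lower of 15 (4 and 1, 3 and 3) and skeletal muscle genes 1 higher and 1 lower of 5 (1 and 1, 1 and 1). The red blood cell, cartilage and skeletal muscle lists had medians of -0.10, -0.15 and -0.05 and means of 0.75, 0.13 and 0.44, so their median and mean differed in sign.

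**Figure D2:**
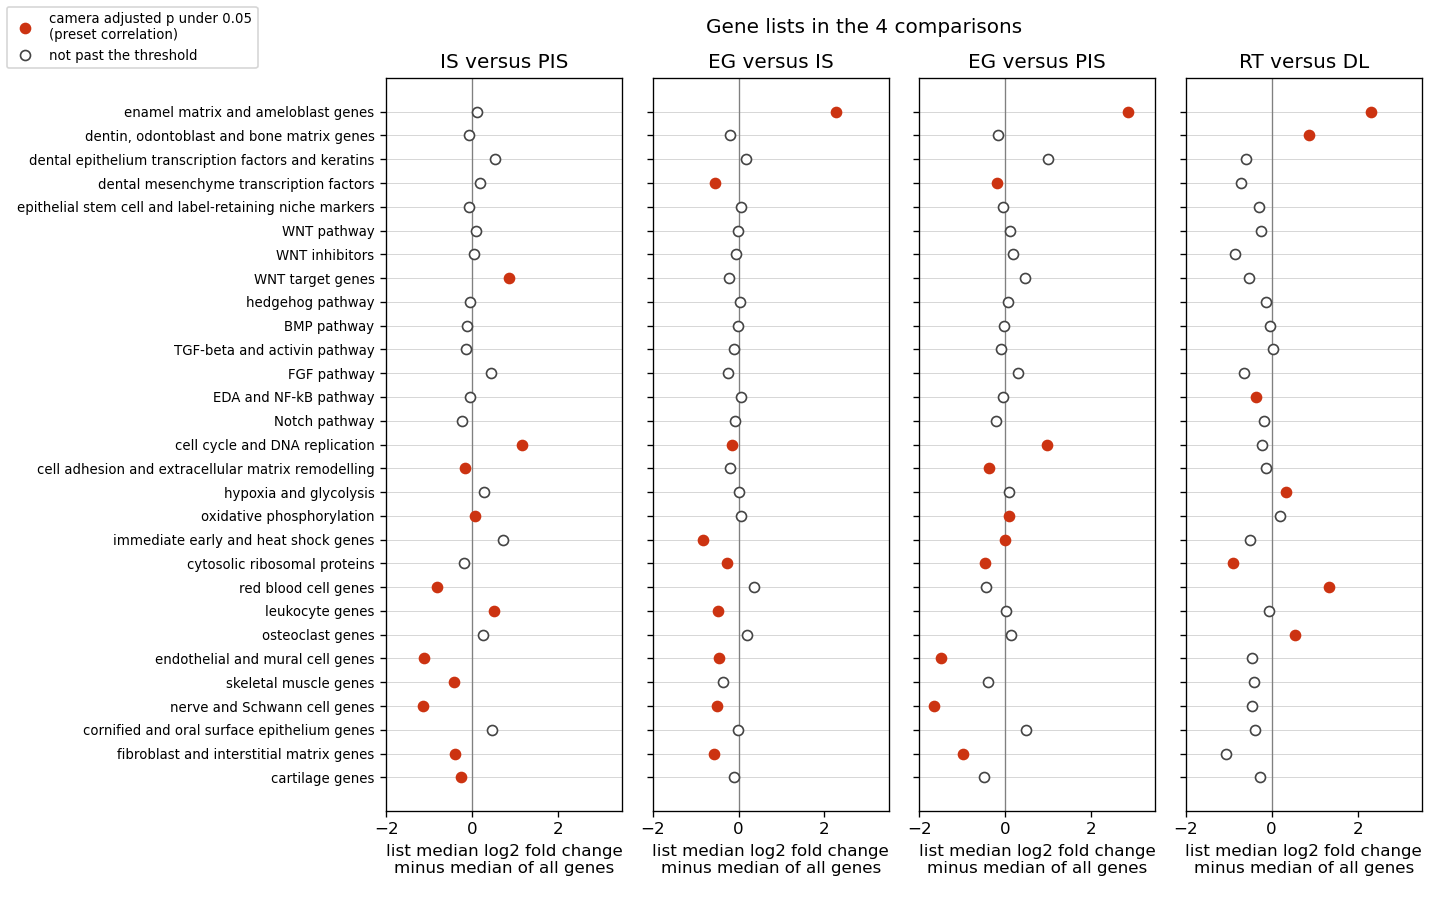
Median log2 fold change of each gene list minus the median of all genes tested, in the 4 comparisons (RT versus DL sets replacement teeth against the mean of the 3 dental lamina stages); filled points passed a camera adjusted p of 0.05 with the preset correlation, and 0 lists passed with an estimated correlation. The enamel list lay highest in EG versus IS, EG versus PIS and RT versus DL, and endothelial and nerve lists lay lowest in EG versus PIS.

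Replacement teeth expressed 7 of 9 enamel genes and 11 of 20 dentin and bone matrix genes above the mean of the 3 dental lamina stages. All 56 ribosomal protein genes and 12 of 15 ectodysplasin and NF-kB genes were lower. Of 12904 genes tested against the mean of the 3 stages, 6038 were called, 1355 higher and 4683 lower. The median gene was lower by 0.24 (log2 fold change -0.24), and after median-ratio scaling 2524 genes were higher and 2327 lower, with 1355 and 2327 called in both analyses. Against EG alone 5659 genes were called, 11.2% of them higher, and against PIS alone 5359, 48.9% of them higher. The count was 3771 with a stricter filter and 1495 at a log2 fold change of at least 1.

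SCNN1D reached 3364 ± 1629 RPKM in RT, beside 84.4 ± 31.7 in EG and 0.959 ± 1.57 in PIS, a log2 fold change of 9.68 ± 0.44 (SE, adjusted p = 7.32e-10) over the dental lamina. AMTN, the amelotin gene of late ameloblasts, reached 443 ± 781 RPKM beside 1.12 ± 0.734 in EG, a change of 7.11 ± 0.73 (SE, adjusted p = 2.21e-06). COL11A2, a fibrillar collagen gene, reached 50.1 ± 30.05 RPKM beside 1.16 ± 0.389 in EG, a change of 5.61 ± 0.32 (SE, adjusted p = 3.46e-09). PHEX, a mineralisation peptidase gene, reached 266 ± 134 RPKM (4.40, adjusted p = 8.97e-07), and ENPP1, whose product makes the mineralisation inhibitor pyrophosphate, 109 ± 60.8 RPKM (4.75, adjusted p = 8.58e-09). FMOD (5.10, adjusted p = 6.29e-09), LOXL4 (5.03, adjusted p = 1.56e-09), the tachykinin gene TAC4 (5.19, adjusted p = 1.28e-09) and CKM (5.19, adjusted p = 5.72e-07) were also among the genes with the greatest rises. The naming rule required ranges without overlap of the greatest rises but not of PHEX, which was named through a list. The ranges of RT and dental lamina libraries did not overlap for any of these 9 genes. Of 12904 genes tested, 1060 had ranges that did not overlap, all of them called. AMBN was at 1505 ± 1708 RPKM and ENAM at 291 ± 516 RPKM in RT, above the mean of the stages (6.07, adjusted p = 0.000487 and 4.18, adjusted p = 0.000965) but not called against EG alone, where the ENAM change was -1.35. The adjusted p against EG was 0.759 for AMBN and 0.295 for ENAM, and ENAM was not called with all 12 dental lamina libraries as 1 group (0.0917). Enamel genes were higher for 7 of 9 measured and lower for 0 (7 and 0 adjusted over the list alone, 8 and 0 after scaling; camera adjusted p = 2.36e-06, adjusted p = 0.312 with an estimated correlation). Dentin and bone matrix genes were higher for 11 of 20 and lower for 5 (11 and 5 adjusted over the list alone, 11 and 3 after scaling; camera adjusted p = 5.31e-05, adjusted p = 0.324 with an estimated correlation).

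The carbonic anhydrase genes CA2 (3.71, adjusted p = 1.94e-05) and CA9 (3.54, adjusted p = 9.99e-09) were higher in RT. Camera placed 3 further lists above other genes. Osteoclast genes were 3 higher and 1 lower of 11 (3 and 1 adjusted over the list alone, 5 and 1 after scaling; camera adjusted p = 0.00556, adjusted p = 0.312 with an estimated correlation). Red blood cell genes were 4 higher and 1 lower of 7 (4 and 1 adjusted over the list alone, 4 and 1 after scaling; camera adjusted p = 0.0049, adjusted p = 0.113 with an estimated correlation). Hypoxia and glycolysis genes were 6 higher and 5 lower of 22 (7 and 6 adjusted over the list alone, 10 and 2 after scaling; camera adjusted p = 0.0234, adjusted p = 0.369 with an estimated correlation). The near-even split of the hypoxia list thus depended on the scaling. HBA1, a haemoglobin gene, was at 325 ± 345 RPKM in RT (2.69, adjusted p = 0.0158), and its call was lost without RT replicate 4 (adjusted p = 0.0581). It was also lost without RT replicates 3 and 5 (adjusted p = 0.0777), against EG alone (0.0633) and against IS alone (0.42). All 56 ribosomal protein genes were lower in RT (56 adjusted over the list alone), 55 also after scaling (camera adjusted p = 1.62e-13, adjusted p = 0.607 with an estimated correlation), with RPS18 at 627 ± 319 RPKM in RT and 1359 ± 114 in EG. Ribosomal protein genes held 6.24% to 12.5% of the RPKM total in RT libraries and 13.9% to 21.0% in dental lamina libraries. The RT libraries differed, with ribosomal list scores of 0.07 and -0.41 in replicates 1 and 2. Replicates 3, 4 and 5 were at -1.14, -1.03 and -1.38, and the lowest dental lamina score was 0.11 (EG replicate 4). Ectodysplasin and NF-kB genes were lower for 12 of 15 (12 adjusted over the list alone), 6 of them also after scaling (camera adjusted p = 0.024, adjusted p = 0.607 with an estimated correlation), with EDA itself at 1.24 ± 0.976 RPKM (-2.33, adjusted p = 0.00115).

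SOX2, a marker gene of dental epithelial stem cells, was at 0.185 ± 0.13 RPKM in RT, below 1.78 ± 0.498 in EG and 2.87 ± 0.79 in PIS (-2.07, adjusted p = 1.42e-07). The BMP and activin antagonist gene FST (-4.16, adjusted p = 2.16e-08), the WNT inhibitor gene SFRP1 (-2.36, adjusted p = 6.14e-06) and the hedgehog inhibitor gene HHIP (-3.01, adjusted p = 2e-05) were lower. So were the Notch ligand gene JAG1 (-1.47, adjusted p = 4.09e-06) and the mesenchymal gene PRRX1 (-3.80, adjusted p = 2.89e-06). CTSW (-4.61, adjusted p = 1.58e-06), LIMK1 (-4.27, adjusted p = 3.01e-07), LUZP2 (-4.01, adjusted p = 3.1e-06) and CLEC3B (-3.97, adjusted p = 3.26e-07) were among the genes with the greatest falls. Mesenchymal transcription factors were 1 higher and 12 lower of 20 (1 and 12 adjusted over the list alone, 1 and 10 after scaling) and dental epithelium genes 0 higher and 5 lower of 16 (0 and 5 adjusted over the list alone, 0 and 5 after scaling), and camera called neither list as deposited (0.112 and 0.374) and both lower after scaling at the preset correlation (0.0127 and 0.0383) but not with an estimated one (0.516 and 0.624). Of cell types, fibroblast genes were 7 higher and 18 lower of 31 (7 and 21 adjusted over the list alone, 7 and 15 after scaling), endothelial and mural genes 1 higher and 16 lower of 28 (1 and 17 adjusted over the list alone, 1 and 8 after scaling) and nerve and Schwann cell genes 4 higher and 10 lower of 16 (4 and 10 adjusted over the list alone, 4 and 8 after scaling). Camera called none of these 3 as deposited (0.267, 0.118 and 0.945), and after scaling it called the first 2 lower at the preset correlation (0.0207 and 0.0207) but not with an estimated one (0.644 and 0.759). LEF1 (-1.72, adjusted p = 0.000369) and AXIN2 (-0.79, adjusted p = 0.000452) were lower and SHH was not called (0.40, adjusted p = 0.761). Against PIS alone SHH was called higher (3.32, adjusted p = 0.0339), and its direction was reversed against EG alone (-2.12), with array weights (-0.43) and without RT replicate 1 (-0.10) or 2 (-0.50). BMP4 was higher (1.14, adjusted p = 0.00481), a call lost with RT replicates 3 and 5 left out together (adjusted p = 0.0707). MSX1 was lower as deposited (-0.56, adjusted p = 0.0344) and not called after scaling (-0.31, adjusted p = 0.306). Its call was also lost without IS replicate 2 (adjusted p = 0.0644), EG 2 (0.0513), RT 1 (0.0799), RT 2 (0.093) or RT 5 (0.077). It was lost without an expression filter (0.0533), after quantile normalization (0.111), with array weights (0.216) and with a replicate block (0.0598). It was lost as well without PIS replicates 4 and 5 (0.0632) and with all 12 dental lamina libraries as 1 group (0.111), and against EG alone its direction was reversed (0.04, adjusted p = 0.902).

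Replacement teeth differed among themselves in enamel and dental epithelium genes. The enamel list score was 2.82, 3.65 and 3.07 in RT replicates 1, 2 and 4, and 1.21 and -0.08 in replicates 3 and 5. The EG libraries were at 0.89 to 2.50, so RT replicate 5 lay below every EG library. The dental epithelium list score was 0.14, 0.35 and -0.26 in RT replicates 1, 2 and 4, and -1.72 and -1.17 in replicates 3 and 5. The dentin and bone matrix score was 0.06, 0.25 and 0.87 in replicates 1, 2 and 4 and 0.96 and 1.47 in replicates 3 and 5, with replicate 4 closer to replicate 3 than to 1 or 2. The collagen gene COL1A1, chosen after its values were seen, was at 3675, 6355 and 14279 RPKM in RT replicates 1, 2 and 4 and at 21057 and 27679.7 RPKM in replicates 3 and 5. With replicates 3 and 5 left out together, 3160 genes were called between RT and dental lamina, an alternative chosen after seeing the data.

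**Figure D3:**
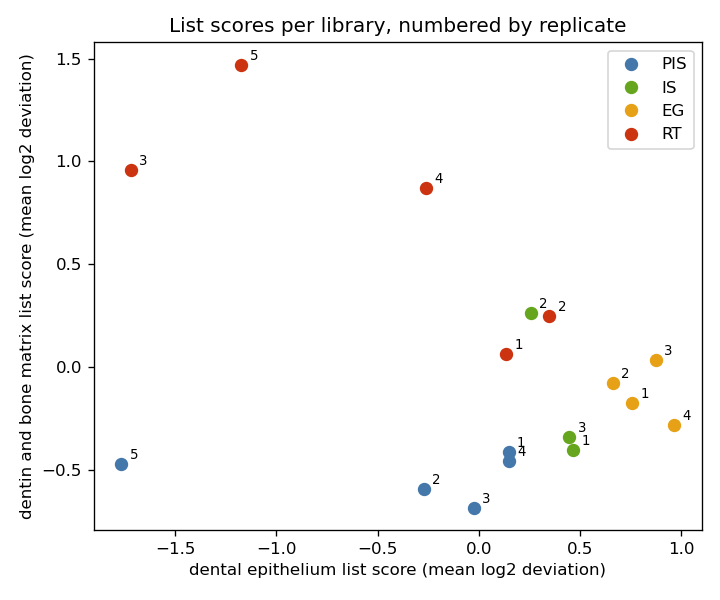
Score of the dental epithelium list (horizontal) against the score of the dentin and bone matrix list (vertical), each the mean log2 deviation of its members from their average over the libraries, with 1 point per library numbered by replicate. RT replicates 3 and 5 (-1.72 and -1.17) and PIS replicate 5 (-1.77) had the lowest dental epithelium scores.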

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

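The tests of other cell types, of carried-over RNA with enamel genes included, of the endothelial genes under scaling and of the top genes' share within RT were chosen only after the results they address were seen. Single libraries far from their group were sought in 522 groups of 4 or 5 libraries, by the gap from the extreme library to the nearest other as a share of the group's range. The share passed the 95% limit of Dixon's test in 39 groups, where chance gives about 1 in 20.

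Of the dental lamina's vessel-wall genes, 19 of 28 were called lower in EG than in PIS and 1 (CNN1) higher. A factor common to all genes of a library cancels in the list score minus the library's median gene. That score differed by -1.51 (EG minus PIS, exact two-sided permutation p = 0.0159 over 126 assignments), which argues against scaling between libraries. The check repeats median-ratio scaling, after which all 19 lower calls were already known to hold. The list was taken up because it fell in these same libraries, so the p-values of its scores are not independent evidence. The endothelial minus leukocyte score differed by -1.47 (exact two-sided permutation p = 0.00794, adjusted p = 0.0265 over 10 scores). Leukocytes alone differed by 0.30 (exact two-sided permutation p = 0.0159) and fibroblasts by -0.58 (exact two-sided permutation p = 0.00794). Nerve, at -0.89, did not pass (exact two-sided permutation p = 0.0556). Leukocyte genes thus did not share the fall. A single list that did not fall, while fibroblast genes did, cannot set aside a lower share of surrounding tissue in EG. Mean scores of red blood cell, osteoclast and surface epithelium genes were higher in the same exact permutation test, by 0.75 (p = 0.0159), 0.39 (p = 0.00794) and 0.72 (p = 0.0317). The median gene was itself 0.34 higher in EG, so the leukocyte and osteoclast differences were close to the shift of all genes. The red blood cell list had members called in both directions and a median opposite in sign to its mean. Its score therefore does not speak for or against fewer vessels. The haemoglobin gene HBA1, looked up after its values were seen, was at 25.9 to 57.4 RPKM in the EG libraries. It was at 2.5 to 9.42 RPKM in PIS replicates 1 to 4 but at 261 in PIS replicate 5, so it does not settle the question either. The most abundant endothelial and mural members were TAGLN (74.9 ± 34.5 RPKM in PIS, 13.8 ± 6.69 in EG) and EGFL7 (37.7 ± 10.8 and 21.1 ± 2.59), which fell, and CNN1 (31.6 ± 3.5 and 40.2 ± 3.58), which did not. Of these 28 members, 1 is in another list. Fewer vessels and mural cells around the lamina in early growth, or less of that tissue dissected with it, may account for much of the pattern, though not for CNN1, and were not told apart by any value here.

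PIS replicate 4 held SHH and SP6 at 23.5 and 21.1 RPKM, beside at most 0.241 and 0.426 in the other PIS libraries. On 962 genes separating the groups its median position from PIS (0) to IS (1) was 0.351, with other PIS libraries at -0.293 to 0.157 and IS libraries at 0.814 to 1.14. Those libraries chose the genes and set 0 and 1, and no IS library was held out for comparison. The position thus argues only weakly against an IS library under a PIS label. Over all genes, Spearman's rho of PIS replicate 4 was 0.967 with IS replicate 2, 0.965 with EG replicate 2 and at most 0.964 with a PIS library. PIS replicate 3 likewise had a higher rho with IS replicate 2 (0.966) than with any PIS library (at most 0.963). A closer match outside the group was thus not particular to PIS replicate 4. Of the 5 most abundant genes high in EG, including AMBN, ENAM and CALB1, none exceeded the other PIS libraries by more than 0.126% of its EG level, which argues against RNA of the EG libraries as sampled. Over 62 genes high in EG the median share was 16.2%, with quartiles 3.45 and 28.4, where SHH needed 41.7%. That spread leaves open whether tissue in an early growth state without enamel expression, from the same lamina or carried over, may have entered this library.

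The median gene was 0.34 higher in EG than in PIS and shifted by -0.24 in RT against the dental lamina. Scaling to the RPKM total without the 100 genes that were in the top 50 of any library left -0.0297 in RT, as a few abundant genes taking much of the signal would give. Scaling to the whole total left -0.227 in RT. Within RT, however, replicates 1 and 2 had the largest shares in those genes (46.9% and 40.8%) and median genes near the average (-0.0229 and 0.00119), beside 36.2% and 39.8% and -0.227 and -0.349 in replicates 3 and 5 (Spearman's rho 0.50, n = 5), so this source stays open. The same step left 0.142 of the EG shift and scaling to the whole total 0.182, and among 568 genes at a mean of 50 RPKM or more, where the pseudocount matters little, the EG shift was 0.173. Most of the fall from 0.34 to 0.142 thus came with the whole total, before the abundant genes were left out. The RPKM totals were 211231 to 236600 in PIS and 242243 to 263363 in EG libraries. Abundant genes may cover a small part of the EG shift and the pseudocount another part. What remains cannot be told apart from a shift of most genes between the stages.

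For each count of called genes, the real grouping gave the most genes among the splits tried, which argues against chance. With 35 to 100 splits, and libraries not known to come from separate animals, chance is not excluded. For the stages 1 of 100 splits gave as many (5764, next 2518). It was 1 of 56 for IS versus PIS (3166, next 821) and 1 of 35 for EG versus IS (273, next 10). It was 1 of 100 for EG versus PIS (6404, next 4014) and 1 of 100 for RT versus dental lamina (6038, next 1962).

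EG replicate 1 was the extreme library most often (11 times). Its low values, each with the nearest other EG library and the gap's share of the range, were ACTG2 (5.35 RPKM, next 19.5, share 0.859), CSF1R (1.55 RPKM, next 2.61, share 0.888), COL6A2 (107 RPKM, next 167, share 0.955), FAP (3.66 RPKM, next 6.0, share 0.884), CFD (18.2 RPKM, next 57.8, share 0.88), COL4A1 (15.1 RPKM, next 32.1, share 0.889) and OGN (4.05 RPKM, next 13.3, share 0.839). Its high values were TOP2A (21.6 RPKM, next 14.5, share 0.915), BMP7 (19.7 RPKM, next 13.1, share 0.864) and ENO1 (300.5 RPKM, next 237, share 0.896). Its fibroblast list score was -0.55 (next -0.015, share 0.831). EG replicate 2 was high in TNC (33.1 RPKM, next 20.5, share 0.838), EG replicate 3 low in SP5 (10.6 RPKM, next 14, share 0.885) and EG replicate 4 high in KLF2 (25.7 RPKM, next 18.7, share 0.888). EG replicate 4 also had a high osteoclast list score of 0.22 (next 0.00369, share 0.901).

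PIS replicate 5 (7 times) was low in AXIN2 (6.9 RPKM, next 13.1, share 0.821), UQCRC1 (19.6 RPKM, next 25.2, share 0.785), WLS (22 RPKM, next 38.9, share 0.845) and PPL (2.03 RPKM, next 6.47, share 0.731) and high in TPM2 (156 RPKM, next 122, share 0.774) and HBA1 (261 RPKM, next 9.42, share 0.732). Its dental epithelium list score was -1.77 (next -0.27, share 0.78). PIS replicate 4 (7 times) was high in FGF3 (0.496 RPKM, next 0.0792, share 0.787), SHH (23.5 RPKM, next 0.241, share 0.898), CA6 (6.71 RPKM, next 0.32, share 0.815) and SP6 (21.1 RPKM, next 0.426, share 0.836) and low in DTX1 (1.53 RPKM, next 1.88, share 0.772), HSPB1 (2.56 RPKM, next 6.75, share 0.788) and CTSW (3.71 RPKM, next 27.3, share 0.749). PIS replicate 2 was low in MSX1 (32.8 RPKM, next 61.3, share 0.784) and ITGB3 (1.14 RPKM, next 1.99, share 0.824), PIS replicate 1 low in TNFRSF11B (27.7 RPKM, next 45.6, share 0.768) and PIS replicate 3 high in LIMK1 (182 RPKM, next 54.9, share 0.745).

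Among replacement teeth, RT replicate 1 was high in FGF3 (24.5 RPKM, next 1.56, share 0.717) and low in ITGB3 (4.54 RPKM, next 8.55, share 0.716). RT replicate 2 was low in BMP4 (4.46 RPKM, next 12, share 0.833), NKD1 (3.27 RPKM, next 6.14, share 0.744) and TPM2 (25.2 RPKM, next 42.7, share 0.756). The stem cell niche list score of RT replicate 4 was -0.00761 (next -0.38, share 0.895).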

How the results depend on the processing

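Leaving out PIS 4 and 5 together or RT 3 and 5 together, and the estimated correlation after scaling, were chosen only after seeing the data. Main counts were 5764 (stages), 3166 (IS versus PIS), 273 (EG versus IS), 6404 (EG versus PIS) and 6038 (RT), and values not given stayed within 1.5 times of them. The cause of a change was not tested unless the setting itself removed genes or libraries. In that order, the stricter filter, which tests fewer genes, gave 3574, 1992, 119, 3982 and 3771. Median-ratio scaling gave 3548 for the stages, 1477 for IS and 4084 for EG versus PIS, and quantile scaling 3665, 1546 and 4025. Array weights gave 4850 for IS versus PIS and 4015 for EG versus IS. A minimum log2 fold change of 1 left 797 for IS, 1725 for EG versus PIS and 1495 for RT. With only the groups compared in the fit, IS versus PIS gave 1494 and EG versus IS 940, and EG versus IS gave 107 with all 17 libraries and 597 without PIS 4 and 5. RT gave 3160 without RT 3 and 5. Leaving out 1 library gave 4306 (EG 1) to 5826 (PIS 1) for the stages, 978 (IS 1) to 3343 (PIS 1) for IS and 4756 (EG 1) to 6542 (PIS 1) for EG versus PIS, 69 (IS 2) to 439 (PIS 5) for EG versus IS and 4627 (RT 3) to 6531 (PIS 5) for RT. IS versus PIS gave 1309 without IS 3, and EG versus IS 139 and 106 without IS 1 and 3 and 109, 180, 87 and 146 without EG 1 to 4.

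Whether replicate numbers pair the libraries was not settled. Of 22 same-numbered pairs, 8 had a correlation over 0.1 (-0.476 to 0.358), without a test against other pairs. For 5 of 17 libraries the best match in another group had their number. With the replicate block the counts were 4946, 2232, 286, 5909 and 5599. Of 116 list tests 37 were called, 0 with an estimated correlation (0 also after median-ratio scaling), 58 with fry (20 of the 37), 37 after median-ratio (26 of the 37) and 34 after quantile scaling (24 of the 37), with 0 in the opposite direction. Lists called only after median-ratio scaling were FGF and ribosomal proteins (IS versus PIS) and WNT targets (EG versus PIS). In RT they were dental epithelium, dental mesenchyme, WNT inhibitors, FGF, cell cycle, oxidative phosphorylation, endothelial and fibroblast genes. Named genes called under every alternative numbered 32 of 52 (IS versus PIS), 7 of 25 (EG versus IS), 50 of 57 (EG versus PIS) and 41 of 54 (RT).

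Signs reversed for 7 gene results, each with an adjusted p of 0.172 or more in the reversed fit. EG versus PIS AXIN2 (0.09) became -0.25 and -0.22 with median-ratio and quantile scaling, -0.11 with the block and without PIS 5, -0.0826 without PIS 4 and 5, and up to 0.16 without PIS 4. IS versus PIS BMP4 (0.20) became -0.0553 with median-ratio scaling, -0.14 with quantile scaling, -0.0639 with the block and -0.0315 without PIS 5 (0.39 without PIS 4). IS versus PIS MSX1 (-0.17) became 0.00081 without IS 3 (-0.41 without IS 2) and 0.0018 without PIS 4 and 5, and SOX2 (-0.08) became 0.0290 without PIS 2 (-0.19 without PIS 4). In RT against EG alone ENAM (4.18) became -1.35, MSX1 (-0.56) 0.0402 and SHH (0.40) -2.12, and SHH was -0.43 with array weights, -0.10 and -0.50 without RT 1 and RT 2 and 1.31 without RT 5. Depth limits genes near 0 RPKM.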

Other observations

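The genes and values below were chosen after they were seen. Some of the most abundant transcripts of enamel-stage tissue had no gene symbol. LOC100552162L was at 28.1 ± 33.7 RPKM in PIS, 4.82 ± 1.47 in IS, 9996 ± 12322 in EG and 25536 ± 31850 in RT (EG versus IS log2 fold change 9.63, limma adjusted p = 0.00439). In EG it was at 755, 1241, 10885 and 27102 RPKM in replicates 1 to 4, the libraries with AMBN at 35.3, 133, 928 and 1858 RPKM. In RT it reached 72106 RPKM in replicate 1 and 34.7 in replicate 5. AMISG014190 was at 2764 ± 1596 RPKM in RT and 91.5 ± 15.4 in EG (RT versus dental lamina 6.12, adjusted p = 7.32e-10). AMISG002215 was at 172 ± 72.5 RPKM in EG and 0.123 ± 0.177 in RT (-4.86, adjusted p = 7.19e-06).

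CKM, a muscle creatine kinase gene, was at 0.0599 ± 0.045 RPKM in IS, 21.9 ± 10.9 in EG and 95.4 ± 21 in RT. Of the 5 measured skeletal muscle genes, CKM was the only 1 higher in RT than in the dental lamina, and 3 were lower. The immediate early gene FOS ranged from 5.03 RPKM in PIS replicate 1 to 1360.4 RPKM in IS replicate 2. HBA1 ranged from 2.5 RPKM in PIS replicate 1 to 917 RPKM in RT replicate 4.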
